A study of Homo sapiens with 22 samples.

How the data were processed

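Gene expression was measured in cultured primary human keratinocytes, the main cells of the epidermis grown from tissue and not an established cell line. The cells had been left without cytokine or treated for 24 h with IL-17 at 200 ng/ml, with TNF-α at 1 or 10 ng/ml, or with IL-17 and TNF-α together. The labels give no subtype of IL-17. RNA was amplified, labelled with biotin and hybridised to Illumina bead arrays, on which each probe is a short sequence carried by many beads, and each array measured 1 sample in 1 colour. There were 22 arrays in 6 groups, with 5 arrays each for control and IL-17 and 3 arrays for every other group. Groups and replicate numbers were taken from the treatment and ID labels, so that the replicates of a group are separate culture IDs.

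The deposited intensity table held, per the file headers, a summarized signal intensity and a detection p-value for each of 48802 probes on each array. How the authors summarized beads into these values is not given in the sources used here. The deposited value table held the authors' processed values of the same arrays, which the values themselves show to be on a log2 scale, quantile normalized and without background correction. Within every array its order of probes was that of the raw intensities (lowest Spearman correlation 1 over 48801 shared probes), its sorted values lay within 0.0374 of the mean sorted log2 intensity, and every column median rounded to 6.13. It was not centred per gene. Per the submitters' processing notes the software lumi was used, with no version and no role stated. No value column belonged to a sample outside these 22.

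Arrays carry no count that would give a depth, so their number limits the precision. From 22.5% to 28.2% of all probes on an array had a detection p below 0.01. The labels place the arrays in 3 named batches, which differed in brightness. The median raw intensity was 76.1 to 87.8 on the 8 arrays of batch 1, 62.8 to 67.7 on the 8 arrays of batch 2 and 63.5 to 66.3 on the 6 arrays of batch 3. The share of detected probes was 26.6% to 28.2%, 22.5% to 25.4% and 24.3% to 25.2% in those batches.

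Intensities were processed with limma 3.58.1 in R 4.3.3. The neqc function corrected the background by normexp, with the moments of the negative controls inferred from the detection p-values, added an offset of 16, and applied quantile normalization and log2. Probes were named from the platform annotation, in which 28096 probes had 1 gene symbol, 13 had several and 20693 had no listed gene. Of the named probes, 28057 were found through their gene number in a table of reference genes (assembly GRCh38.p14), and 0 symbols needed an update. No genome build is named for the arrays, so no coordinates are given. A probe was kept when it was detected at p below 0.01 on at least 3 arrays, which left 12835 probes, and each gene was read from its kept probe with the highest mean. This gave 9961 genes, of which 2358 had several kept probes. XIST and genes of the Y chromosome were removed before any test.

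A linear model with 1 mean per group was fitted over all 22 arrays with lmFit and eBayes, so that all groups shared 1 estimate of the spread. Differences are log2 changes with their standard errors (SE), and p-values are two-sided and adjusted by the Benjamini-Hochberg method over the 9961 genes of a comparison. A gene was called at an adjusted p below 0.05. The 13 comparisons set each treatment against control, the higher against the lower TNF-α dose with and without IL-17, each combination against its single treatments, and, at each dose, the combination against the sum of both single log2 changes (the interaction). A gene whose probe was not detected on any array of a group has only a bound there. Its fold is then written as at least the bright group's mean over the dim group's mean of, per array, the lowest signal among detected probes or the probe's own signal if higher, on normalized log2 values. A gene detected on some but not all arrays of a group has no bound. Its change rests in part on signals below that lowest signal (the detection floor).

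Gene lists were fixed for neutrophil chemokines, other chemokines, antimicrobial peptides and proteins, NF-kB targets and feedback genes, IL-1 family cytokines, other cytokines and growth factors, interferon-stimulated genes, antigen processing, complement and acute phase proteins, differentiation and cornification, basal keratinocyte and hemidesmosome genes, hyperproliferation-associated keratins, the cell cycle, proteases and serpins, receptors and signalling of IL-17 and TNF, cholesterol synthesis, oxidative stress and metal response, unfolded protein and heat stress, and glycolysis and hypoxia. Further lists held markers of macrophages, lymphocytes, fibroblasts, melanocytes, Langerhans cells and endothelial cells, and of keratinocyte identity. The 24 lists with measured members were tested with camera at a preset inter-gene correlation of 0.01 in 7 comparisons (the 5 with control and both interactions), with adjustment over all 168 tests. Camera was also run with an estimated correlation, and fry as a test of each list on its own. Counts of called members are given over all genes and adjusted over the list alone. List medians are given also at the bound where this value differs, with each member that was not well above background in a group set to its bound (0 where both groups were dim). No such value was computed for the interactions.

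Design, gene lists, alternatives and the rule for named genes were fixed before the data were examined. For each comparison with control the rule takes the 10 largest rises and 5 largest falls among called genes with the same sign in every replicate number, and up to 3 called members per list (or up to 2 members, as values, where none was called). For every other comparison it takes the 5 largest rises and 5 largest falls among called genes. Genes known only by a LOC number, a cluster or a reading frame label were passed over. Probes of near-identical families (the SPRR2 genes, SERPINB3 and SERPINB4, S100A7 and S100A7A, DEFB4A and its copies) were not tested for cross-hybridisation, so these genes are uncertain as separate genes.

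The ID label gives a culture number from 1 to 5 that recurs across treatments, and numbers 1 to 3 cover every treatment. All arrays of culture 1 lay in batch 1. For culture 2, control and IL-17 lay in batch 1 and all groups with TNF-α in batch 2. For culture 3, TNF-α alone lay in batch 3 and the other groups in batch 2. Within cultures 2 and 3 the difference of TNF-α alone from control was thus also a difference between batches. The same held for the combinations within culture 2. Before any calls were compared, the deviations of the arrays from their group means were correlated. All 47 pairs with the same number had a positive correlation (0.281 to 0.896, median 0.612), against a median of -0.274 for the 152 pairs with different numbers. The 16 same-number pairs in different batches had a median of 0.533. The first principal component of normalized values held 41.5% of the variance, and the culture number accounted for 96.2% of it. The culture number therefore paired the arrays. No label states a model, so the fit without it stayed the main one, and values with the culture number as a block stand beside those it changed. The main fit sets TNF-α groups of cultures 1 to 3 against control and IL-17 groups of cultures 1 to 5. Differences between cultures therefore enter its changes and their SE. The fits that leave out a replicate number have no block either. A low count or a lost call in such fits does not show that genes did not respond. Values within a batch carry culture differences too, since TNF-α groups there share their cultures with controls only in part or not at all.

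Alternatives were the culture number as a block, the batch as a block, log2 intensities with quantile normalization and no background correction, the authors' deposited log2 values, no detection filter (18775 genes), replicates 1 to 3 alone, leaving out each replicate number in turn, and, for the interactions, a linear scale. Both blocks together, the left-out replicates for lists and for the overlap, list tests for 4 more comparisons, changes with each array at its detection floor or above, and splits of the interactions within culture numbers were added after seeing the data. The procedure was tested on simulated arrays with the same design, spread and 9961 genes, of which 100 were changed 2-fold and 100 were changed 4-fold. Of these, 59% and 92% were recovered for IL-17 against control, 31% and 91% for 10 ng/ml TNF-α, 32% and 84% for IL-17 with 10 ng/ml TNF-α, and 7% and 62% for the interaction at 10 ng/ml, with 1, 0, 3 and 0 false calls. With the culture number as a block the shares were 97% and 100%, 76% and 100%, 81% and 100%, and 40% and 100%, with 7, 8, 11 and 4 false calls. In the simulation culture differences were drawn separately for each gene and batches did not differ. The real arrays had culture differences shared across genes and batches of unlike brightness, so these false calls may not carry over to them. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.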

Results

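Transcript levels were measured on 22 bead arrays of primary human keratinocytes in 6 groups. Control and IL-17 (200 ng/ml) had 5 arrays each. TNF-α at 1 ng/ml, TNF-α at 10 ng/ml, and IL-17 with each of these doses had 3 arrays each, all after 24 h. The series concerns psoriasis, and the comparisons ask how keratinocytes respond to IL-17, to TNF-α, and to both cytokines at once. A sample's depth is not defined on arrays, and their number limits the precision. Changes are log2 differences of group means with the standard error (SE), levels are normalized log2 intensities ± SD, and limma gave all p-values of single genes. Replicates are numbered cultures, and the labels place the arrays in 3 batches.

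A protocol label mentions macrophages although all samples are labelled keratinocytes, so markers of both were looked up. All 12 measured markers of keratinocyte identity were detected on all 22 arrays. KRT14 and KRT5, the keratins of basal epidermal cells, stood at mean levels of 14.04 and 13.55, at percentiles 99.9 and 99.7 of all genes. Of the macrophage and myeloid markers, CD68, a lysosomal protein that other cells also make, was detected on 22 arrays at 8.94 ± 0.47, CD14 on 17 and LYZ on 4. The other 12 with a probe, among them CD163, CSF1R, AIF1 and TYROBP, were detected on 0 arrays. The macrophage list rose with IL-17 and 1 ng/ml TNF-α (3 measured of 16, median 0.59, or 0.57 at the bound, camera adjusted p = 0.043), and its adjusted p was 0.094 with an estimated correlation. None of these 3 members passed limma's test, and 0 had a raw p below 0.05. That list's median was -0.11 within batch 1 and 1.09 within batch 2, and with the batch as a block its adjusted p was 0.052. Without a block no call was made in any of 7 comparisons for markers of fibroblasts (4 measured of 12, smallest adjusted p = 0.25), melanocytes (2 of 10, 0.45) or Langerhans cells (2 of 8, 0.39). Lymphocyte and endothelial markers (12 and 8 listed) had 0 members detected on at least 3 arrays.

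IL-17 against control asks what IL-17 alone does, and it raised antimicrobial and cornified envelope genes. DEFB4A (probe ILMN_2048043), a secreted antimicrobial defensin, rose from 4.43 ± 0.04, not well above background, to 9.35 ± 0.82 (n = 5 each), which is at least 14.5-fold higher (log2 change 4.92, SE 0.36, adjusted p = 5.1e-08). SPRR2A (probe ILMN_1795359), a cross-linked protein of the cornified envelope, rose from 9.09 ± 0.54 to 13.14 ± 0.43, 16.6-fold (4.06, SE 0.29, adjusted p = 5.1e-08). IL36G, an IL-1 family cytokine of the epidermis, rose from 7.63 ± 1.37 to 11.11 ± 0.50 (3.48, SE 0.44, adjusted p = 2.4e-04). ZC3H12A, an RNase that degrades inflammatory mRNAs, rose 8.05-fold (adjusted p = 3.4e-07), and NFKBIZ, a nuclear cofactor of NF-kB, rose 6.77-fold (adjusted p = 0.0013).

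Antimicrobial peptides and proteins rose as a list with IL-17 (3 of 15 over all genes, 6 adjusted over the list alone, 7 over all genes with the culture number as a block, median 0.95, or 0.91 at the bound, adjusted p = 1.8e-34). S100A9 and S100A8, which form the metal-binding protein calprotectin, rose by 1.48 (SE 0.21) and 1.47 (SE 0.23). Differentiation and cornification genes also rose (4 of 40, 5 adjusted over the list alone, 7 blocked, median 0.28, adjusted p = 1.3e-14), led by SPRR2A, SPRR2E (2.77), SPRR2F (2.77) and SPRR2B (2.76, or 2.47 with each array at its detection floor or above). SPRR2C, which is not on that list, rose by 3.63. The NF-kB list rose (2 of 15, 2 adjusted over the list alone, 3 blocked, median 0.60, adjusted p = 1.6e-18). IL-1 family cytokines (1 of 7, 2 adjusted over the list alone, median 0.57, adjusted p = 8.1e-10) and complement and acute phase genes (1 of 9, 4 adjusted over the list alone, median 0.46, or 0.00 at the bound, adjusted p = 3.3e-11) rose too. In the complement list SAA1, an acute phase protein, rose by 2.14 (SE 0.39, adjusted p = 0.018), or by 1.70 with each array at its detection floor or above. Neutrophil chemokines rose as a list (median 1.52, or 1.03 at the bound, adjusted p = 1.2e-17). Of those 5 genes limma called 0 over all genes (raw p below 0.05 for 5), 5 adjusted over the list alone and 3 over all genes with the block. CXCL8, which attracts neutrophils, was 1.89 higher (SE 0.49, adjusted p = 0.37, and 1.1e-04 with the block).

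Smaller list changes with IL-17 were a rise of other cytokines (limma 0 of 12, raw p below 0.05 for 3, 1 adjusted over the list alone, median 0.38, or 0.21 at the bound, adjusted p = 6.4e-04). Proteases and serpins rose (limma 0 of 18, raw p below 0.05 for 4, 1 adjusted over the list alone, median 0.31, or 0.12 at the bound, adjusted p = 0.0014, but adjusted p = 0.11 with an estimated correlation). SERPINB4, a protease inhibitor, was 3.14 higher (SE 0.67, adjusted p = 0.080, and 6.3e-06 with the block). Interferon-stimulated genes fell as a list (median -0.16, adjusted p = 0.040), with adjusted p = 0.59 with an estimated correlation and 0.078 with the batch as a block, and limma called 0 of 28 members (raw p below 0.05 for 0). Within batches 1, 2 and 3 the interferon median was -0.32, 0.05 and -0.18.

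In all, IL-17 changed 14 genes, 14 up and 0 down, and with the culture number as a block 51 genes, 49 up and 2 down. ANKK1 and SOX7 were the called genes outside the rule for named genes, chosen after their values were seen. Without replicate 1 there were 8 called genes and without replicate 2 there were 9. A batch block gave 22, and the 14 genes had a median rise of 2.74, 2.84 and 2.53 within batches 1, 2 and 3. Of the 12 named called genes, 6 were called whichever replicate number was left out (DEFB4A, IL36G, SPRR2A, SPRR2E, SPRR2F and ZC3H12A).

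TNF-α at 1 ng/ml against control asks what a low dose of TNF-α does. It raised IL32 (probe ILMN_1778010), a proinflammatory cytokine, from 5.48 ± 0.37 (n = 5) to 7.72 ± 0.37 (n = 3), 4.74-fold (2.24, SE 0.25, adjusted p = 1.5e-04). RELB, an NF-kB subunit, rose 2.76-fold (1.46, SE 0.24, adjusted p = 0.023). These were the 2 called genes, against 96 with the culture number as a block (81 up, 15 down). With the batch as a second block 54 genes were called. NF-kB targets and feedback genes rose together (1 of 15, 11 adjusted over the list alone, 7 blocked, median 0.86, adjusted p = 2.5e-27). Other cytokines and growth factors rose as well (1 of 12, 3 adjusted over the list alone, median 0.59, adjusted p = 8.9e-09).

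Several further lists rose at 1 ng/ml although limma called 0 of their members over all genes. IL-1 family cytokines did so (raw p below 0.05 for 4 of 7, 2 adjusted over the list alone, 3 blocked, median 1.03, adjusted p = 1.0e-06). There IL36G was 2.07 higher (SE 0.51, adjusted p = 0.30, blocked 2.71 with adjusted p = 6.9e-05) and IL1B, the cytokine IL-1β, was 1.37 higher (SE 0.35, adjusted p = 0.30, blocked 0.018). Interferon-stimulated genes rose (raw p below 0.05 for 6 of 28, 1 adjusted over the list alone, 3 blocked, median 0.61, adjusted p = 1.4e-12), with medians of 1.08, -0.45 and 1.04 within batches 1, 2 and 3. Antigen processing genes, which load peptides onto surface molecules, rose (raw p below 0.05 for 4 of 11, 4 adjusted over the list alone, median 0.27, adjusted p = 8.5e-06), with 0.73, -0.34 and 0.61 within the batches. Other chemokines rose too (raw p below 0.05 for 2 of 6, median 0.81, or 0.62 at the bound, adjusted p = 0.0063). Neutrophil chemokines (raw p below 0.05 for 1 of 5, median 0.41, or 0.00 at the bound, adjusted p = 0.018) were lost with an estimated correlation, at adjusted p = 0.070. Complement and acute phase genes (raw p below 0.05 for 3 of 9, 3 adjusted over the list alone, median 0.22, or 0.00 at the bound, adjusted p = 2.8e-04) had adjusted p = 0.061 with an estimated correlation. Proteases and serpins (raw p below 0.05 for 6 of 18, 1 adjusted over the list alone, 5 blocked, median 0.11, adjusted p = 0.0012) had adjusted p = 0.11 with an estimated correlation. Their member MMP9, a gelatinase, was 3.20 higher (SE 0.69, adjusted p = 0.17, blocked 4.18 with adjusted p = 5.5e-08).

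Differentiation genes rose at 1 ng/ml (limma 0 of 40, raw p below 0.05 for 4, 3 adjusted over the list alone, median 0.12, adjusted p = 0.019, adjusted p = 0.60 with an estimated correlation), with 0.41, 0.98 and -0.21 within batches 1, 2 and 3. Keratinocyte identity genes rose (limma 0 of 12, raw p below 0.05 for 0, median 0.27, adjusted p = 0.016, adjusted p = 0.25 with an estimated correlation and 0.65 with the culture number as a block). Cell cycle genes fell (limma 0 of 34, raw p below 0.05 for 0, median -0.34, adjusted p = 0.0029, adjusted p = 0.70 with an estimated correlation), with 0.27, -1.84 and 0.20 within batches 1, 2 and 3. Antimicrobial genes were called with the culture number as a block (adjusted p = 5.8e-06, against 0.12 without it), at adjusted p = 0.076 with the block and an estimated correlation. Leaving out a replicate number gave 0 called genes without replicate 1 (limma, raw p below 0.05 for 251), 1 without replicate 3, and 4 without replicate 4 or 5, so neither IL32 nor RELB was called in all 5 cases. None of these 5 fits had a block, so differences between cultures stayed in their SE. A batch block gave 34 called genes, and IL32 and RELB had a median rise of 2.06, 1.90 and 1.57 within batches 1, 2 and 3, where TNF-α arrays of batches 2 and 3 share no replicate number with controls.

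TNF-α at 10 ng/ml against control asks the same at the higher dose. MMP9 (probe ILMN_1796316) rose from 6.49 ± 1.67 (n = 5) to 11.18 ± 0.49 (n = 3), 25.8-fold (4.69, SE 0.69, adjusted p = 0.0023), and 50.9-fold with the culture number as a block (5.67, SE 0.29). IL32 rose to 8.35 ± 0.51, 7.34-fold (2.88, SE 0.25, adjusted p = 2.1e-06). C1QTNF1, a secreted protein related to complement C1q, rose 9.60-fold (adjusted p = 3.5e-04). Called members of the NF-kB list (8 of 15, 13 adjusted over the list alone, 12 blocked, median 1.36, adjusted p = 4.0e-38) included TNFAIP3, which limits NF-kB signalling (2.86, SE 0.40), IRAK2, a kinase of IL-1 receptor signalling (2.96, SE 0.48), and SOD2, the mitochondrial superoxide dismutase (2.31, SE 0.35). Falls were called for 2 genes, RHOBTB3 (-1.39, SE 0.26) and GPX3, a secreted glutathione peroxidase (-1.26, SE 0.24).

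Interferon-stimulated genes rose at 10 ng/ml (2 of 28, 6 adjusted over the list alone, 17 blocked, median 0.89, adjusted p = 1.7e-16), among them RSAD2, an antiviral enzyme (1.25, SE 0.23), and the transcription factor IRF1 was 2.03 higher (SE 0.43, adjusted p = 0.033). RSAD2, detected on 1 of 5 control arrays, rose by 0.82 with each array at its floor or above. Interferon medians in batches 1 to 3 were 1.23, -0.16 and 1.24, the last 2 without paired controls. Antigen processing genes rose (2 of 11, 3 adjusted over the list alone, median 0.18, adjusted p = 1.5e-05), with TAP1, a peptide transporter, at 1.11 (SE 0.20) and TAPBP at 1.02 (SE 0.18). Other chemokines rose as a list (limma 0 of 6, raw p below 0.05 for 4, 3 adjusted over the list alone, median 1.61, or 1.32 at the bound, adjusted p = 1.0e-05), and CXCL10, which attracts T cells, was 3.04 higher (SE 0.88, adjusted p = 0.26, blocked 0.0056). IL-1 family cytokines rose (2 of 7, 3 adjusted over the list alone, median 1.02, adjusted p = 1.1e-06), with IL36G at 2.75 (SE 0.51, blocked 3.38) and IL1B at 2.18 (SE 0.35). Other cytokines rose (3 of 12, 4 adjusted over the list alone, 6 blocked, median 0.87, or 0.81 at the bound, adjusted p = 1.0e-11), among them TNFSF10, a death ligand (2.08), and HBEGF, a growth factor of the EGF family (1.93). Complement genes rose (2 of 9, 3 adjusted over the list alone, median 0.42, or 0.34 at the bound, adjusted p = 1.2e-05), with CFB, a complement protease, at 2.25 (SE 0.48) and C1R, at least 2.85-fold higher than a control not well above background (adjusted p = 0.0031). Proteases and serpins rose (2 of 18, 4 adjusted over the list alone, 7 blocked, median 0.38, or 0.25 at the bound, adjusted p = 4.7e-06).

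Receptors and signalling genes of IL-17 and TNF rose at 10 ng/ml (1 of 20, 3 adjusted over the list alone, median 0.21, adjusted p = 0.0022), and so did neutrophil chemokines (limma 0 of 5, raw p below 0.05 for 2, 2 adjusted over the list alone, median 0.55, or 0.00 at the bound, adjusted p = 0.0027). CXCL8 was 2.22 higher (SE 0.57, adjusted p = 0.14, blocked 1.5e-05). Cell cycle genes fell (limma 0 of 34, raw p below 0.05 for 0, median -0.41, adjusted p = 0.0084, adjusted p = 0.71 with an estimated correlation), with 0.25, -1.79 and 0.16 within batches 1, 2 and 3. Oxidative stress and metal response genes fell (limma 0 of 16, raw p below 0.05 for 0, median -0.30, or -0.28 at the bound, adjusted p = 0.042, adjusted p = 0.070 with an estimated correlation, 0.051 with the batch as a block). Called with the culture number as a block alone were antimicrobial genes (2 of 15 over all genes and 2 adjusted over the list alone without it, adjusted p = 1.6e-05 against 0.086), differentiation genes (3.4e-04 against 0.26) and cholesterol synthesis (0.039). Their blocked adjusted p was 0.089, 0.38 and 0.18 with an estimated correlation.

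In all, 10 ng/ml TNF-α changed 37 genes (35 up, 2 down), and 292 with the culture number as a block (238 up, 54 down). With the batch as a second block 194 genes were called. There were 3, 14 and 13 called genes without replicates 1, 2 and 3, and of 24 named called genes IL32 alone was called in all 5 cases. A batch block gave 119 genes, and the raised genes had a median change of 1.83, 1.92 and 1.38 within batches 1, 2 and 3. Genes raised by both IL-17 and 10 ng/ml TNF-α numbered 3 (IL36G, S100A8 and S100A9), against 0.049 for independent draws, and 20 with the culture number as a block. With different controls for each treatment the overlap was 0, but 14 and 2 raised genes (limma) are too few to tell. It was 0 too without replicate 1, 2 or 3. Across genes, which are not independent replicates, the covariance of both changes was 0.0284 against 0.0166 in simulated arrays without changes that share controls. Their correlation r was 0.313 against 0.341, or 0.308 against 0.408 with the culture number as a block. Only the covariance exceeded the simulation. Different controls gave covariance -0.0117 and r -0.0897, where culture differences enter.

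IL-17 with 1 ng/ml TNF-α against control asks what both cytokines do together. DEFB4A rose to 11.67 ± 0.61 (n = 3), at least 72.3-fold (7.24, SE 0.42, adjusted p = 1.1e-09). SERPINB4 (probe ILMN_1782716) rose from 5.54 ± 0.76 to 12.18 ± 1.25, 99.2-fold (6.63, SE 0.77, adjusted p = 2.8e-05), or 53.8-fold with the culture number as a block. IL19 (probe ILMN_1799575), a cytokine of the IL-10 family, rose from 4.33 ± 0.06, not well above background, to 10.72 ± 1.21, at least 37.5-fold (6.39, SE 0.70, adjusted p = 1.6e-05). IL36G rose by 5.04 (SE 0.51, blocked 5.67) and SPRR2A by 4.91 (SE 0.33), with adjusted p = 6.0e-06 and 1.1e-08. S100A7A, a psoriasin-related protein, rose at least 7.31-fold and IL23A, a subunit of the cytokine IL-23, at least 9.36-fold over controls not well above background (adjusted p = 2.8e-05 and 9.4e-05). Called falls were IGFL2 (-2.70, SE 0.54, blocked -2.08), ID3, an inhibitor of helix-loop-helix transcription factors (-1.73, SE 0.27), CPA4 (-1.65), RHOBTB3 (-1.61) and MSTO1 (-1.17). IGFL2, RHOBTB3 and MSTO1 were each detected on 1 of 3 treated arrays. With each array at its detection floor or above their changes were -2.33, -1.12 and -0.72.

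With this combination neutrophil chemokines rose (3 of 5, 5 adjusted over the list alone, median 2.31, or 1.75 at the bound, adjusted p = 5.4e-11), CXCL8 by 3.43 (SE 0.57, adjusted p = 0.0016) and CXCL2 by 2.39 (adjusted p = 0.044). Antimicrobial genes rose (7 of 15, 7 adjusted over the list alone, 12 blocked, median 2.10, or 1.82 at the bound, adjusted p = 4.6e-18), including PI3, an elastase inhibitor (3.22, SE 0.62, blocked 3.94). NF-kB genes rose (7 of 15, 12 adjusted over the list alone, median 1.46, adjusted p = 7.0e-27), among them ZC3H12A (3.97, SE 0.29), NFKBIZ (3.54, SE 0.47) and IRAK2 (2.95, SE 0.48). Other cytokines rose (5 of 12, 8 adjusted over the list alone, 9 blocked, median 1.20, or 1.00 at the bound, adjusted p = 1.1e-16), and so did IL-1 family cytokines (2 of 7, 6 adjusted over the list alone, 5 blocked, median 1.30, adjusted p = 9.6e-09), IL1B by 2.52. Complement and acute phase genes rose (5 of 9, 7 adjusted over the list alone, median 2.21, or 1.18 at the bound, adjusted p = 2.4e-15), with CFB at 3.88 (SE 0.48) and SAA1 at 2.98. Proteases and serpins rose (3 of 18, 7 adjusted over the list alone, 9 blocked, median 0.45, or 0.32 at the bound, adjusted p = 9.9e-06). CCL20, which attracts dendritic cells and T cells, rose 10.6-fold (adjusted p = 0.046), while other chemokines were not called as a list (1 of 6, 2 adjusted over the list alone, adjusted p = 0.32). CCL20 was detected on 2 of 5 control arrays. Its log2 change was 3.41, or 2.85 with each array at its detection floor or above.

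Differentiation genes rose as a list with this combination (6 of 40, 10 up and 1 down adjusted over the list alone, 17 up and 5 down blocked, median 0.38, adjusted p = 1.8e-06), with adjusted p = 0.22 with an estimated correlation. Receptors and signalling genes rose (1 of 20, 1 adjusted over the list alone, median 0.16, adjusted p = 0.018, adjusted p = 0.061 with an estimated correlation). Cell cycle genes fell (limma 0 of 34, raw p below 0.05 for 0, median -0.48, adjusted p = 0.0084), but adjusted p was 0.71 with an estimated correlation and 0.41 with the batch as a block, and the median was 0.36 and -1.23 within batches 1 and 2. Interferon-stimulated genes (median -0.05, or -0.02 at the bound, adjusted p = 0.65) and antigen processing genes (0.00, 0.95) were not called, and GBP2, a GTPase induced by interferon, was 2.90 higher (SE 0.73, adjusted p = 0.067, blocked 1.93 with adjusted p = 2.1e-04). In all, 92 genes were called, 84 up and 8 down, and 473 with the culture number as a block (310 up, 163 down). Without replicate 1 there were 36 and without replicate 2 there were 53, and 15 of 32 named called genes were called in all 5 cases, DEFB4A, IL19, S100A7A and SPRR2A among them. With the batch as a block 182 genes were called, and raised genes had a median change of 2.40 and 2.42 within batches 1 and 2.

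**Figure D1:**
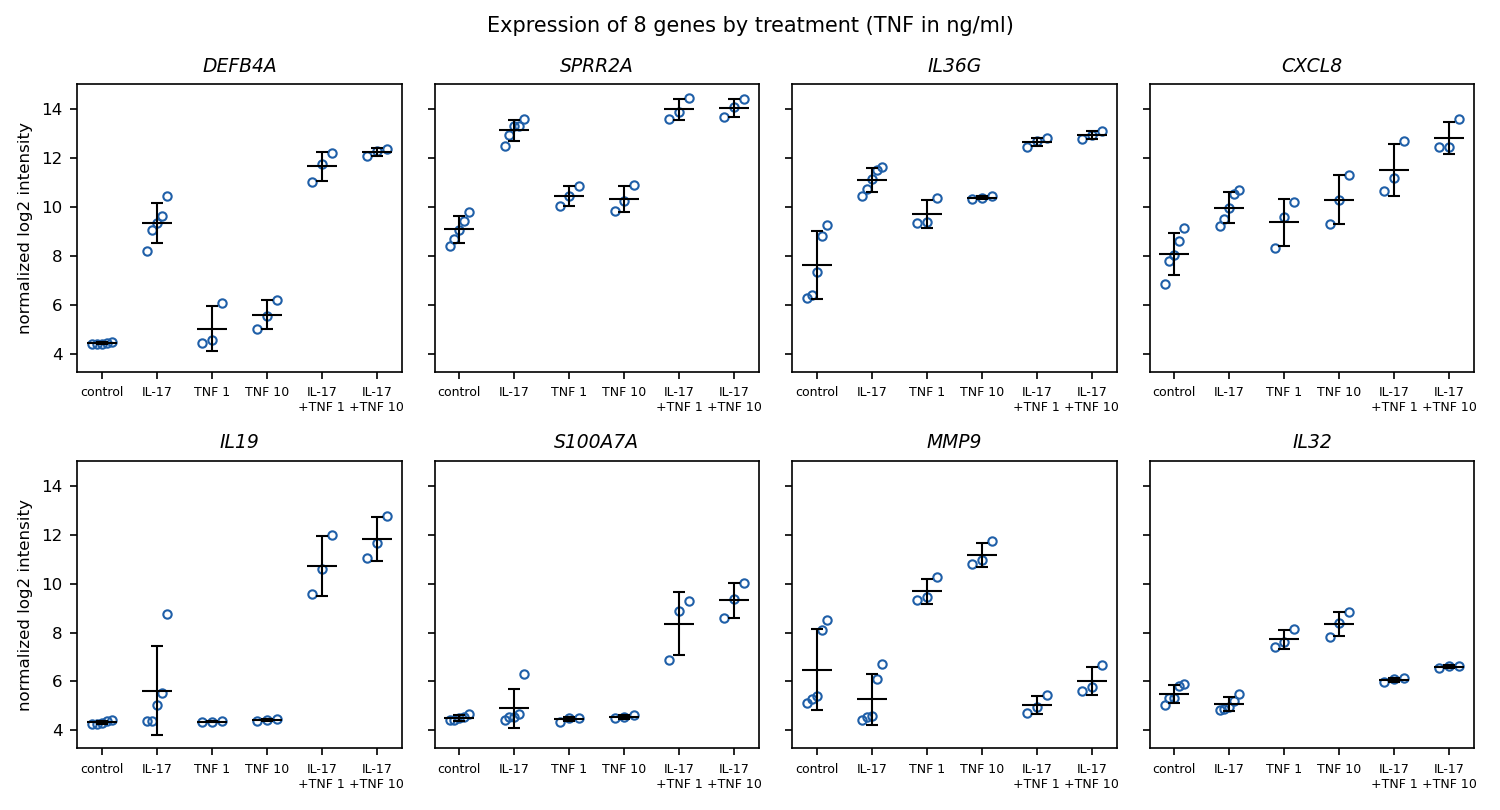
Normalized log2 intensity (vertical axis) of 8 genes in the 6 treatment groups, with a point per array and a bar for the mean ± SD. With IL-17 and 10 ng/ml TNF-α, DEFB4A stood at 12.25 ± 0.15 and IL19 at 11.83 ± 0.88, while MMP9 stood at 6.02 ± 0.58 there and at 11.18 ± 0.49 with that TNF-α dose alone.

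IL-17 with 10 ng/ml TNF-α against control changed the most genes of the 5 treatments. DEFB4A rose to 12.25 ± 0.15 (n = 3), at least 108-fold (7.82, SE 0.42, adjusted p = 2.4e-10). IL19 rose to 11.83 ± 0.88, at least 80.9-fold (7.50, SE 0.70, adjusted p = 8.1e-07), and SERPINB4 rose 143-fold (7.16, SE 0.77, adjusted p = 4.9e-06), or 77.7-fold with the culture number as a block. CXCL8 (probe ILMN_2184373) rose by 4.76 (SE 0.57, adjusted p = 1.7e-05). KYNU (probe ILMN_1746517), an enzyme of tryptophan breakdown, rose at least 14.2-fold and S100A7A (probe ILMN_1673191) at least 14.3-fold over controls not well above background (adjusted p = 3.1e-06 and 8.1e-07). The 5 largest falls were IGFL2 (-2.75, blocked -2.13), TNNI2, at least 3.95-fold lower and not well above background after treatment (adjusted p = 0.029), ID3 (-2.29, SE 0.27), MIR503HG (adjusted p = 0.0036) and CPA4 (adjusted p = 0.0042).

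All 5 neutrophil chemokines measured rose (5 over all genes, 5 adjusted over the list alone, median 2.73, adjusted p = 3.5e-13), CXCL6 by at least 7.52-fold (adjusted p = 0.030). Other cytokines rose (9 of 12, 10 adjusted over the list alone, median 2.25, or 2.15 at the bound, adjusted p = 7.1e-21), among them IL23A at least 16-fold and IL6 by 3.31 (SE 0.77, adjusted p = 0.025). NF-kB genes rose (11 of 15, 13 adjusted over the list alone, median 1.98, adjusted p = 1.4e-28), with ZC3H12A at 4.03 and SOD2 at 3.88. Antimicrobial genes rose (7 of 15, 8 adjusted over the list alone, 13 blocked, median 2.05, adjusted p = 7.5e-18), with S100A7, the antimicrobial protein psoriasin, at least 7.13-fold higher (adjusted p = 2.3e-07). Complement genes rose (6 of 9, 7 adjusted over the list alone, median 2.49, or 1.76 at the bound, adjusted p = 3.9e-14), with CFB at 4.76 (SE 0.48) and C1R at least 4.61-fold higher. IL-1 family cytokines rose (2 of 7, 6 up and 1 down adjusted over the list alone, 6 blocked, median 1.58, adjusted p = 1.1e-07). IL36G rose 39.7-fold (61.5-fold blocked) and IL1B by 3.09. Proteases and serpins rose (6 of 18, 8 adjusted over the list alone, 11 up and 1 down blocked, median 0.50, or 0.34 at the bound, adjusted p = 1.3e-06), with SERPINB3 at 3.49 and PLAT, the tissue plasminogen activator, at 3.00. Receptors and signalling genes rose (1 of 20, 1 adjusted over the list alone, median 0.34, adjusted p = 8.8e-04).

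Other chemokines were not called as a list at this dose (2 of 6, 2 adjusted over the list alone, adjusted p = 0.065, blocked 0.047), although CCL20 rose 20.2-fold (adjusted p = 0.0036) and CXCL16 by 1.64 (adjusted p = 0.042). The log2 change of CCL20 was 4.33, or 3.77 with each array at its detection floor or above. Differentiation genes rose (6 up and 1 down of 40, 13 up and 2 down adjusted over the list alone, 21 up and 5 down blocked, median 0.47, adjusted p = 3.2e-06, adjusted p = 0.23 with an estimated correlation), SPRR2A by 4.98 and SPRR2E by 4.08. SPRR2C, which is not on that list, rose by 5.01. Cell cycle genes fell (limma 0 of 34, raw p below 0.05 for 0, 4 down blocked, median -0.61, adjusted p = 0.0028), but adjusted p was 0.70 with an estimated correlation and 0.21 with the batch as a block, and the median was 0.32 and -1.46 within batches 1 and 2. Interferon-stimulated genes (2 of 28, 2 adjusted over the list alone, median 0.19, adjusted p = 0.069) and antigen processing (1 of 11, 1 adjusted over the list alone, median 0.03, or 0.00 at the bound, adjusted p = 0.72) were not called, while GBP2 rose by 3.44 (blocked 2.47) and IRF1 by 1.78 (adjusted p = 0.011 and 0.029). The change of KRT15, a basal keratin, was -1.94 (SE 1.18, adjusted p = 0.56, blocked 0.0015), and that of ITGA6, an integrin that binds the basement membrane, -0.95 (SE 0.46, adjusted p = 0.43, blocked 0.0029). KRT75 rose by 1.85 (adjusted p = 0.025). In all, 189 genes were called, 161 up and 28 down, and 945 with the culture number as a block (578 up, 367 down). Without replicate 1 there were 71 and without replicate 2 there were 88, and 21 of 38 named called genes were called in all 5 cases, CXCL8, KYNU and SOD2 among them. With the batch as a block 347 genes were called, and raised genes had a median change of 2.06 and 2.04 within batches 1 and 2.

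**Figure D2:**
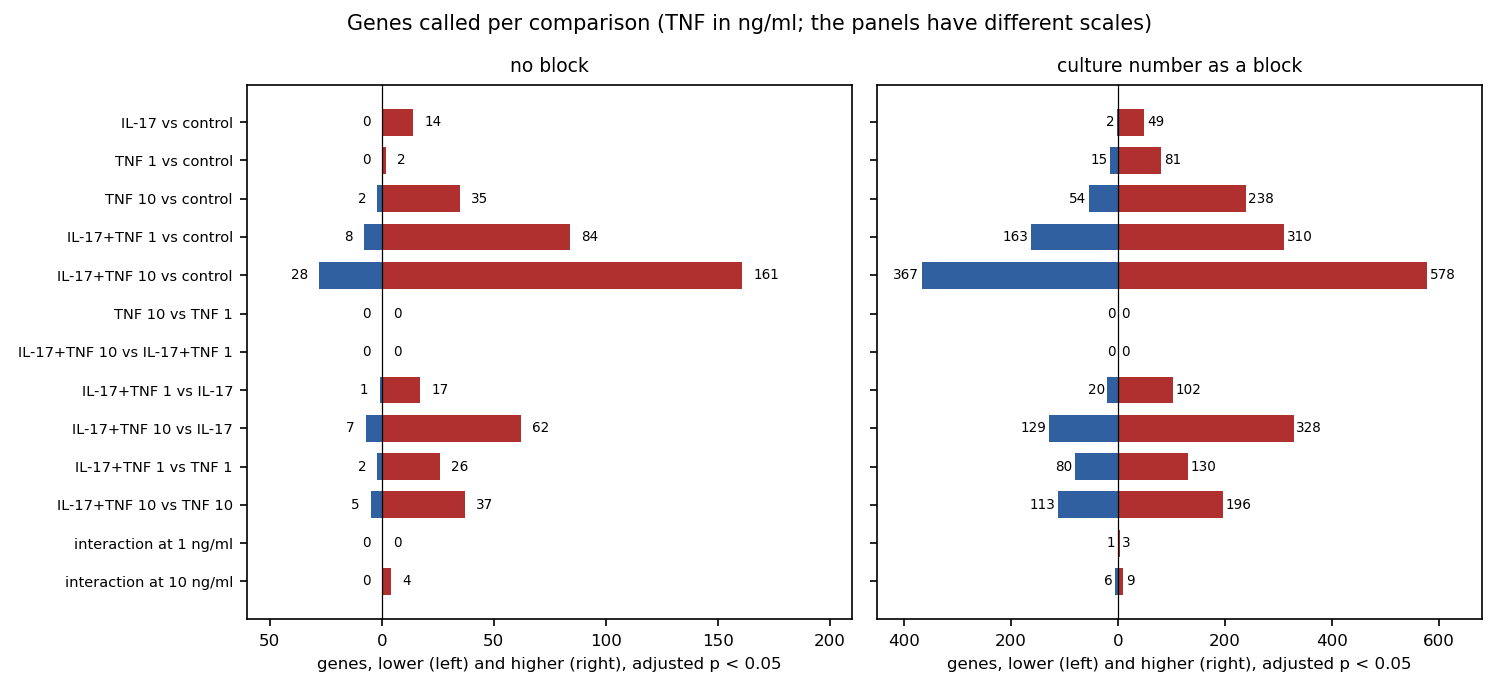
Number of genes with higher and lower levels (horizontal axis) in each of 13 comparisons, in panels with different scales for the fit without a block and with the culture number as a block. IL-17 with 10 ng/ml TNF-α against control gave 161 higher and 28 lower genes without a block, and 578 and 367 with it.

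The higher and lower TNF-α doses were set against each other to ask what a larger dose adds. IL32 stood at 8.35 ± 0.51 with 10 ng/ml and 7.72 ± 0.37 with 1 ng/ml (n = 3 each), MMP9 at 11.18 ± 0.49 and 9.69 ± 0.50. With IL-17 present, IL19 stood at 11.83 ± 0.88 and 10.72 ± 1.21, and DEFB4A at 12.25 ± 0.15 and 11.67 ± 0.61. No single gene was called by limma between doses, neither without IL-17 (0 genes, raw p below 0.05 for 53, or 383 with the culture number as a block) nor with it (0 genes, raw p below 0.05 for 61, or 321 with the block). The blocked count over adjusted p was 0 in both cases as well, and the batch as a block gave 0 (raw p below 0.05 for 227 and 197).

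Adding TNF-α to IL-17 asks what TNF-α contributes beside IL-17. IL19 rose from 5.62 ± 1.82 with IL-17 alone (n = 5) by 5.10 with 1 ng/ml (SE 0.70, adjusted p = 0.0020) and by 6.21 with 10 ng/ml (adjusted p = 4.7e-05). It was detected on 2 of the 5 IL-17 arrays, and with each array at its detection floor or above the rises were 4.45 and 5.56. S100A7A, detected on 1 of these 5 arrays, rose by 3.46 and 4.43 (adjusted p = 0.0016 and 2.9e-05), or by 2.63 and 3.60 with the floor. KYNU rose by 2.87 and 3.98 (0.011 and 9.3e-05) and CFB by 2.78 and 3.65 (0.015 and 2.1e-04). KYNU was detected on 2 of the 5 IL-17 arrays, and its rises were 2.30 and 3.40 with the floor. C1QTNF1 rose by 2.41 with 1 ng/ml (adjusted p = 0.011), and SERPINB4 by 4.02 with 10 ng/ml (adjusted p = 0.012, blocked 3.14). ID3 fell by 1.40 and 1.96 (adjusted p = 0.028 and 3.2e-04). The other called falls with 10 ng/ml were, among genes of the rule, MRPL1 (-1.76), GPX3 (-1.35), DLEU1 (-1.05) and RPF1 (-0.94).

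With 1 ng/ml, 18 genes were called against IL-17 alone, 17 up and 1 down, and 122 with the culture number as a block. With 10 ng/ml there were 69, 62 up and 7 down, and 457 with the block. At 1 ng/ml the count was 0, 3, 11, 7 and 9 without replicates 1 to 5 (limma, raw p below 0.05 for 513 in the case of 0), and 0 of 6 named genes were called in all 5 cases. At 10 ng/ml it was 18, 25, 42 and 39 without replicates 1, 2, 4 and 5, and 4 of 10 named genes were called in all 5 cases (ID3, IL19, KYNU and S100A7A). The counts were 35 and 153 with the batch as a block, and all called genes had the same sign within batches 1 and 2.

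Adding IL-17 to TNF-α asks what IL-17 contributes beside TNF-α. DEFB4A rose by 6.63 (SE 0.47, adjusted p = 4.7e-08) beside 1 ng/ml and by 6.65 (adjusted p = 4.4e-08) beside 10 ng/ml (n = 3 each). It was detected on 1 of 3 arrays of either TNF-α dose alone, and with each array at its detection floor or above the rises were 5.86 and 6.43. IL19 rose at least 36.3-fold and at least 77.8-fold, and S100A7A at least 7.07-fold and at least 13.7-fold, over TNF-α alone, where neither was well above background (adjusted p = 1.5e-04, 1.0e-05, 2.0e-04 and 1.0e-05). SERPINB4 rose by 5.03 and 5.49 (adjusted p = 0.0063 and 0.0017), and SPRR2C by 4.14 and 4.33 (0.0053 and 0.0019). MMP9 fell from 9.69 ± 0.50 to 5.04 ± 0.37 beside 1 ng/ml (-4.65, SE 0.77, adjusted p = 0.0053) and from 11.18 ± 0.49 to 6.02 ± 0.58 beside 10 ng/ml (-5.16, SE 0.77, adjusted p = 0.0013). With IL-17 and 1 ng/ml MMP9 was detected on 1 of 3 arrays, and with the floor its change there was -4.10. IL32 fell from 7.72 ± 0.37 to 6.06 ± 0.09 beside 1 ng/ml (-1.66, SE 0.28, adjusted p = 0.0053), and beside 10 ng/ml by 1.75 (SE 0.28, adjusted p = 0.0019). Further falls beside 10 ng/ml were CPA4 (-1.98, adjusted p = 0.038), ID3 (-1.51, adjusted p = 0.019) and RSAD2, at least 1.75-fold lower and then not well above background (adjusted p = 0.033).

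Against 1 ng/ml TNF-α 28 genes were called, 26 up and 2 down, and 210 with the culture number as a block. Against 10 ng/ml 42 were called, 37 up and 5 down, and 309 with the block. The counts were 3 and 7 without replicates 1 and 2 at the lower dose, and 11 and 14 at the higher one. DEFB4A was called in all 5 cases at the lower dose (1 of 7 named genes), and DEFB4A, IL19 and S100A7A at the higher one (3 of 10). With the batch as a block 49 and 100 genes were called, and all called genes had the same sign within batches 1 and 2.

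The interaction asks whether the combination departed from the sum of both single log2 changes. At 10 ng/ml it was positive for 4 genes, IL19 (6.11, SE 0.98, adjusted p = 0.021), S100A7A (4.38, SE 0.63, adjusted p = 0.0086), S100A7 (2.55, SE 0.46, adjusted p = 0.049) and IL17C, an epithelial cytokine of the IL-17 family (2.02, SE 0.37, adjusted p = 0.049). On a linear scale, with each single treatment set at the detection floor or above, the combination was on average 23.7, 6.60, 3.23 and 1.67 times the sum of both single treatments for these genes. Without a floor, the combination minus both single treatments plus control was positive in each of 3 replicates for 109 of the 161 genes this combination raised (67.7%) and negative in each for 7, and at 1 ng/ml it was positive for 64 of 84 (76.2%). These genes were picked for their rise with the combination, which favours an excess, and among genes raised with the culture number as a block the shares were 306 of 578 (52.9%) and 158 of 310 (51.0%).

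Lists above the sum at 10 ng/ml were antimicrobial genes (2 of 15, 3 adjusted over the list alone, median 0.74, adjusted p = 5.8e-06, adjusted p = 0.15 with an estimated correlation) and other cytokines (2 of 12, 3 up and 1 down adjusted over the list alone, median 0.59, adjusted p = 5.8e-06). Neutrophil chemokines (limma 0 of 5, raw p below 0.05 for 2, median 1.02, adjusted p = 8.2e-04) and complement genes (limma 0 of 9, raw p below 0.05 for 2, 1 adjusted over the list alone, median 0.51, adjusted p = 5.4e-05) lay above it too. These medians have no bound. In 10 ng/ml TNF-α against control, 6 of 15 antimicrobial genes, 3 of 5 neutrophil chemokines and 6 of 9 complement genes were not well above background in at least 1 group. Interferon-stimulated genes lay below the sum (limma 0 of 28, raw p below 0.05 for 1, 2 down blocked, median -0.37, adjusted p = 1.6e-05), with adjusted p = 0.19 with an estimated correlation, or 0.029 when the culture number was a block as well, and a median of -0.56 and -0.15 within batches 1 and 2. Antigen processing genes lay below it (limma 0 of 11, raw p below 0.05 for 1, 1 down adjusted over the list alone, median -0.31, adjusted p = 1.1e-04). At 1 ng/ml antimicrobial genes (limma 0 of 15, raw p below 0.05 for 3, 3 adjusted over the list alone, median 0.21, adjusted p = 0.0048, adjusted p = 0.41 with an estimated correlation) and complement genes (limma 0 of 9, raw p below 0.05 for 2, 1 adjusted over the list alone, median 0.66, adjusted p = 2.2e-04, adjusted p = 0.059 with an estimated correlation) lay above the sum. Other cytokines did so as well (limma 0 of 12, raw p below 0.05 for 4, 3 up and 1 down adjusted over the list alone, median 0.39, adjusted p = 0.0081, adjusted p = 0.061 with an estimated correlation), with medians of -0.18 and 0.42 within batches 1 and 2. Interferon-stimulated genes (limma 0 of 28, raw p below 0.05 for 1, median -0.43, adjusted p = 8.6e-05, adjusted p = 0.24 with an estimated correlation, or 0.033 with the block as well) lay below it, with -0.58 and -0.14 within the batches. Antigen processing genes (limma 0 of 11, raw p below 0.05 for 0, median -0.45, adjusted p = 1.2e-04) lay below it, with -0.66 and 0.09 within the batches.

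With the culture number as a block the interaction was called for 15 genes at 10 ng/ml (9 up, 6 down) and for 4 at 1 ng/ml (3 up, 1 down), where limma without a block called 0 (raw p below 0.05 for 112). At 10 ng/ml the count was 0, 2, 1, 0 and 2 without replicates 1 to 5 (limma, raw p below 0.05 for 125 and 90 in the cases of 0). S100A7A was called in 3 of these 5 cases, IL19 and S100A7 in 1 and IL17C in 0. The authors' deposited values, which lack background correction, gave a call for IL19 and S100A7A and none for S100A7 and IL17C. Log2 and quantile normalized values without background correction gave a call for IL19, S100A7A and S100A7 above the sum, none for IL17C, and 1 below the sum, for MMP9. In all they had 3 above and 1 below, and with the batch as a block 4 and 1. At 1 ng/ml 1 gene was called without replicate 2.

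**Figure D3:**
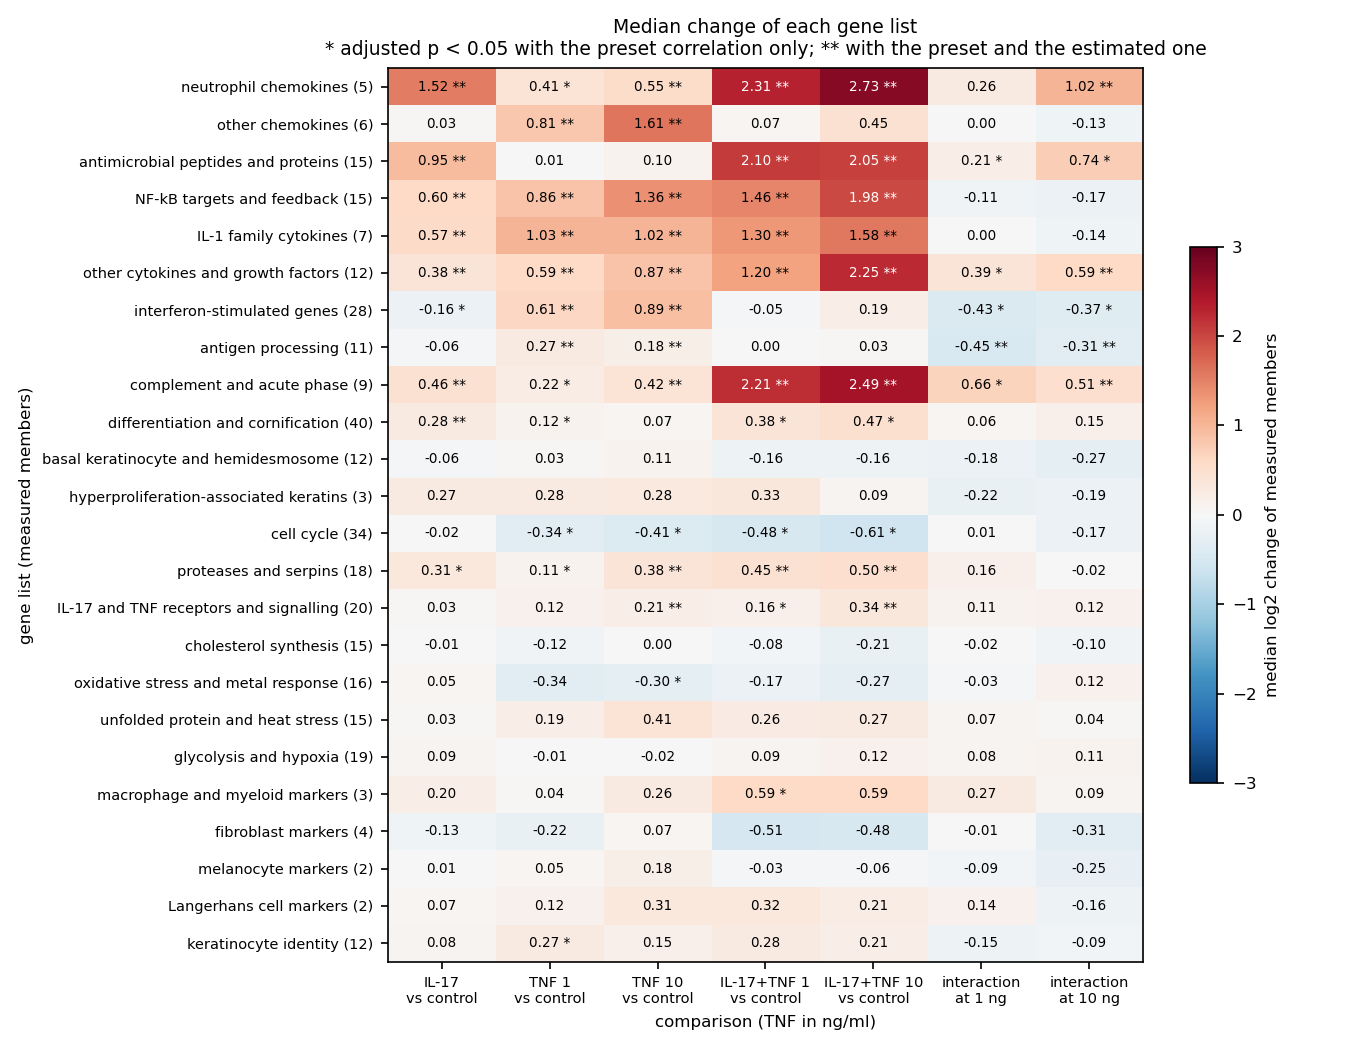
Median log2 change (colour and printed value) of 24 gene lists (rows) in 7 comparisons (columns), with * for lists called by camera at the preset correlation only and ** for lists called with an estimated correlation too. Neutrophil chemokines had medians of 1.52 with IL-17, 0.55 with 10 ng/ml TNF-α and 2.73 with both.

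Over all 168 list tests 65 were called, 43 of them also with an estimated correlation, and the lists given above without such a p held with it. Basal keratinocyte genes (12 measured, smallest adjusted p = 0.094), hyperproliferation-associated keratins (3, 0.17), cholesterol synthesis (15, 0.49), unfolded protein and heat stress (15, 0.42) and glycolysis and hypoxia (19, 0.084) were called in 0 of the 7 comparisons. With the culture number as a block 75 lists were called. The block and an estimated correlation together ended 6 calls that the latter alone left, which were other cytokines with IL-17 (adjusted p = 0.11), other chemokines with 1 ng/ml TNF-α (0.071), neutrophil chemokines (0.071) and receptors (0.16) with 10 ng/ml, receptors with IL-17 and 10 ng/ml (0.061), and neutrophil chemokines at the interaction at 10 ng/ml (0.081). Added calls not yet given were glycolysis with IL-17 and 1 or 10 ng/ml TNF-α (adjusted p = 0.024 and 0.018, or 0.061 and 0.051 with an estimated correlation) and macrophage markers with IL-17 and 10 ng/ml (0.034, or 0.13 with an estimated correlation). At the interaction at 10 ng/ml the blocked calls added were differentiation (0.034), basal (0.047) and cell cycle genes (0.036), with 0.59, 0.22 and 0.61 with an estimated correlation. A batch block gave 69 calls, and 53 of the 65 kept direction in every batch, where cultures can differ. Calls gained with it were glycolysis with IL-17 (0.036) and with both combinations (0.028 and 0.023), other chemokines with both combinations (0.037 and 0.0076), keratinocyte identity at both interactions (0.044 and 0.037), and NF-kB and differentiation genes at the interaction at 10 ng/ml (0.036 and 0.018). The median, mean and test of a list differed in sign for 0 of 65 called and 15 of 103 other lists. Where a called gene had further detected probes, these had the same sign for 4 of 4 with IL-17, 1 of 1 and 9 of 9 with 1 and 10 ng/ml TNF-α, and 23 of 23 and 44 of 48 with the combinations. The opposite sign in the last case belonged to probes of DDR1, HCAR3, LOC646938 and MAFF.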

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

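The counts over other splits of the arrays were planned before the results were seen, except those of the interactions within culture numbers, and every other test in this part was chosen after its result was seen.

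At 10 ng/ml TNF-α the combination with IL-17 exceeded the sum of both single log2 changes for IL19 (6.11), S100A7A (4.38), S100A7 (2.55) and IL17C (2.02) in the fit without a block. No log2 interaction was computed with each array at its detection floor or above. With that floor the rise over IL-17 alone went from 6.21 to 5.56 for IL19 and from 4.43 to 3.60 for S100A7A, so the interactions given are likely too large. Single treatments held at background would raise such a value by construction. With these set at the detection floor or above, the combination was at least 3.64 times their sum in each of 3 replicates for IL19 and S100A7A and 2.80 times for S100A7, while the lowest ratio for IL17C was 0.902. For the first 3 genes the combination thus exceeded a sum on the linear scale, which stays open for IL17C. The ratio does not measure the log2 interaction, so it cannot say how much of that value comes from background. In the deposited values without background correction the interaction was smaller but still past the threshold for IL19 (4.89) and S100A7A (3.06), and for S100A7 it was 1.66 (SE 0.292), without a call there but with one in log2 and quantile normalized values without that step (1.61, SE 0.274), which argues against it as the whole source for these 3 genes. For IL17C it fell from 2.02 (SE 0.37) to 1.07 (SE 0.255) and 1.03 (SE 0.229), and its call ended in both with the smaller change, so for this gene background correction stays open. A joint action of both cytokines on IL19 and S100A7A may underlie their excess, as a hypothesis, while cross-hybridisation between S100A7 and S100A7A was not tested and splits within culture numbers leave chance open.

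Interferon-stimulated genes and MMP9 were lower when IL-17 was added to TNF-α than with TNF-α alone. In replicate 3 the arrays of the combination and of TNF-α alone lay in different batches, unlike those of replicates 1 and 2. For the interferon list the higher of the medians of replicates 1 and 2 was -0.38 beside 10 ng/ml. For MMP9 the highest of 4 differences in these replicates was -4.02. These values argue against batch differences as the sole source of either fall. The interferon median was -0.56 in the deposited values without background correction, so that step does not account for it. A fall of these genes under IL-17 may be biological, as a hypothesis, and for the list it lost its call with an estimated correlation and no block (adjusted p = 0.12 beside 10 ng/ml). Medians per replicate were -0.83, -0.38 and -0.72, and 25, 20 and 23 of 28 members were lower.

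Many more genes passed the threshold with the culture number as a block, such as 945 against 189 for IL-17 with 10 ng/ml TNF-α. Differences between batches alone are unlikely to account for this, since the batch as a block gave 347. Spread between cultures is consistent with it, since the deviations of arrays with the same number in different batches had a median correlation of 0.533, but what differed between cultures is not in the labels.

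Among probes without a listed gene, which no comparison of named genes uses, 11 of 2688 passed the threshold with IL-17 and 10 ng/ml TNF-α against control, 10 up and 1 down, and 83 with the culture number as a block. The largest rise was 7.37 (SE 0.287, adjusted p = 1.2e-14) for probe ILMN_1680965, and the next largest was 2.25 (SE 0.372, adjusted p = 0.0022) for probe ILMN_2407824.

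Other splits of the same arrays into groups of the same sizes were counted where they gave as many genes as the real groups. For IL-17 against control 7 of 100 splits did (14 genes, highest other 2290), so chance is not excluded by this count, while the 15 other splits that part all 5 pairs gave at most 0 genes by limma. The count of 2290 is many times the real one and points to a structure of the samples, in which culture numbers differ. By this count chance is excluded for 1 ng/ml TNF-α (2 of 56 splits, 2 genes, highest other 3), but the highest of the 7 other splits that part 3 pairs was 3 as well, so among splits that keep the pairing it stays open. With the culture number as a block the highest of these 7 splits was 28, against 96 for the real groups. These 7 splits exchange TNF-α and control arrays in some or all of the 3 pairs. They can thus keep much of the real difference with its sign turned, so 28 is not a level that chance alone gives. Over all splits it is also excluded for 10 ng/ml TNF-α (1 of 56, 37 genes, highest other 3), IL-17 with 1 ng/ml (1 of 56, 92 genes, highest other 4) and IL-17 with 10 ng/ml (1 of 56, 189 genes, highest other 5), and for each combination against IL-17 alone (1 of 56 each, 18 and 69 genes, highest others 8 and 10). Most of these splits put arrays of a culture number on the same side, unlike the real groups. Only 7 other splits part 3 pairs in each of these 5 comparisons, too few for a share under 0.05, and their highest counts were 3, 4, 5, 0 and 0, below the real ones, so within the pairing chance is not excluded. With the culture number as a block the highest counts of these splits were 96, 254, 492, 0 and 11. The real groups then gave 292, 473, 945, 122 and 457. These splits too exchange arrays in some or all of the 3 pairs and can keep much of the real difference with its sign turned. Their counts are therefore not levels that chance alone gives, and this comparison does not decide on chance. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. There the real counts and the highest others were 28 and 0 against 1 ng/ml TNF-α, 42 and 0 against 10 ng/ml, 0 and 1 between doses, and 0 and 0 between doses beside IL-17. For the interaction at 10 ng/ml 4 of 100 splits gave as many genes (4 genes, highest other 1508), but when treatments were exchanged only within a culture number 6 of 100 did (highest other 17), so chance is not excluded. With the culture number as a block 7 of 100 such splits gave 15 genes or more (highest other 326). At 1 ng/ml chance is not excluded either (100 of 100, 0 genes by limma, highest other 1938). There, with the culture number as a block, 5 of 100 splits within culture numbers gave 4 genes or more (highest other 75). Counts of 1508 and 1938 again point to the structure of culture numbers.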

How the results depend on the processing

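Both blocks together, the left-out replicates for gene lists and for the overlap, the list tests of 4 more comparisons, changes with each array at its detection floor or above, and splits of the interactions within culture numbers were chosen after seeing the data, and all other alternatives given here before. No gene called in the main fit was called in the opposite direction in another fit. No list call turned with an estimated correlation, with fry, or with the culture number or the batch as a block. In every batch, where cultures can differ, 53 of the 65 called lists kept direction. Across genes, r of the IL-17 and 10 ng/ml TNF-α changes went from 0.313 to -0.0897 with different controls, where culture differences enter. Counts of called genes are given in the order IL-17, 1 ng/ml and 10 ng/ml TNF-α, and IL-17 with each dose, all against control, then 1 and 10 ng/ml added to IL-17, then IL-17 added to 1 and 10 ng/ml. They were 14, 2, 37, 92, 189, 18, 69, 28 and 42, and became 51, 96, 292, 473, 945, 122, 457, 210 and 309 with the culture number as a block, with every gene called without it still called in the same direction. With the batch as a block they were 22, 34, 119, 182, 347, 35, 153, 49 and 100, and with both blocks 67, 54, 194, 446, 940, 139, 451, 237 and 417. Leaving out each replicate number in turn gave 8 to 16, 0 to 4, 3 to 27, 36 to 83, 71 to 182, 0 to 11, 18 to 58, 3 to 26 and 11 to 41. Without background correction 1 ng/ml TNF-α gave 8 genes, and in the authors' deposited values 9. Replicates 1 to 3 alone gave 7 and 24 genes for 1 and 10 ng/ml TNF-α, and 7 and 30 for these doses added to IL-17, with fewer arrays. The interaction at 1 ng/ml (0 genes by limma, raw p below 0.05 for 112) became 4 with the culture number as a block, 8 with both blocks, 1 with replicates 1 to 3 alone, 0 to 1 with a replicate left out and 64 genes with a positive excess on a linear scale. The interaction at 10 ng/ml (4 genes) became 15, 39, 2, 0 to 2 and 109 in the same order, 2 in the deposited values and 1 without a detection filter, where 18775 genes were tested. Both dose comparisons stayed at 0 in every alternative (limma, raw p below 0.05 for 53 and 61). Of the 65 list calls 43 were made with an estimated correlation and 43 by fry, which shared 40 with them, 75 with the culture number as a block (64 shared), 69 with the batch as a block (60 shared), and 58 to 69 with a replicate left out. The overlap of 3 genes became 20 with the block and 0 to 3 with a replicate left out. The linear scale is another measure, and more arrays or genes tested change the power by construction; for the other changes the cause was not tested.

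Of 168 results of named genes, the culture number as a block left 145 on their side of the threshold and brought 23 more past it, the batch as a block kept 155, with 10 gained and 3 lost, and both blocks kept 146, with 22 gained. No background correction kept 153, with 3 gained and 12 lost, the deposited values 153, with 2 gained and 13 lost, no filter 148, with 20 lost, and replicates 1 to 3 alone 116, with 6 gained and 46 lost. Without replicates 1 to 5 there were 83, 109, 123, 139 and 139 kept, with up to 2 gained. Apart from the values given beside the results above, the culture number as a block changed no other call named in the text. Signal over background limits the low end, since a gene detected on no array of a group has a bound there and no fold.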

Other observations

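The dose test at the end was planned before its result was seen, and the list tests and the genes named in this part were chosen after the values were seen.

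When IL-17 was added to TNF-α, 96 further list tests (camera, adjusted over these) gave rises of neutrophil chemokines at 1 ng/ml (limma 0 of 5, raw p below 0.05 for 5, 5 adjusted over the list alone, 3 blocked, median 1.41, adjusted p = 2.6e-09) and 10 ng/ml (2 of 5, 4 adjusted over the list alone, 4 blocked, median 2.48, or 1.64 at the bound, adjusted p = 8.0e-14). Antimicrobial genes rose beside both doses (3 and 4 of 15, 8 and 8 adjusted over the list alone, 10 and 11 blocked, medians 1.37 and 1.56, or 0.97 and 1.11 at the bound, adjusted p = 3.0e-22 and 5.3e-27). Complement genes rose (3 and 4 of 9, 5 and 4 adjusted over the list alone, 5 and 5 blocked, medians 1.17 and 1.43, or 1.01 and 1.41 at the bound, adjusted p = 7.2e-12 each). IL-1 family cytokines rose (1 and 0 of 7 by limma, raw p below 0.05 for 2 and 2, 2 and 1 adjusted over the list alone, 1 and 2 blocked, medians 0.46 and 0.56, adjusted p = 0.0011 and 0.0015). Other cytokines rose (2 up and 1 down, and 3 up and 1 down, of 12, with 3 up and 1 down, and 4 up and 1 down, adjusted over the list alone, medians 0.39 and 0.68, adjusted p = 1.3e-05 and 9.6e-09). These 5 lists held with an estimated correlation, except that other cytokines beside 1 ng/ml had adjusted p = 0.062 when the culture number was a block as well.

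Antigen processing genes fell in the same comparisons (limma 0 and 0 of 11, raw p below 0.05 for 3 and 3, 0 and 2 adjusted over the list alone, 1 and 2 blocked, medians -0.47 and -0.35, adjusted p = 2.6e-05 and 6.2e-05, held with an estimated correlation), with -0.54 and -0.11 within batches 1 and 2 beside 1 ng/ml and -0.36 and -0.16 beside 10 ng/ml. Interferon-stimulated genes fell (limma 0 and 1 of 28, raw p below 0.05 for 4 and 3, 1 and 1 adjusted over the list alone, 8 and 9 down with 1 and 0 up blocked, medians -0.62, or -0.59 at the bound, and -0.60, adjusted p = 1.6e-07 and 8.4e-08). Their adjusted p was 0.13 and 0.12 with an estimated correlation, or 0.015 each with the culture number as a block as well, and their medians were -0.82 and -0.14 within batches 1 and 2 beside 1 ng/ml, and -0.83 and -0.14 beside 10 ng/ml. Further lists lost their call with an estimated correlation. These were NF-kB targets (adjusted p = 1.4e-05 and 0.0015, or 0.13 and 0.28), differentiation (1.5e-05 and 1.1e-08, or 0.28 and 0.15) and proteases (0.0078 and 0.036, or 0.22 and 0.30, and 0.054 beside 10 ng/ml with the culture number as a block), which rose, and basal genes beside 10 ng/ml (0.025, or 0.28), which fell. The protease medians were 0.30 and 0.18, or 0.12 and 0.002 at the bound. Of 18 proteases and serpins, limma called 2 up and 1 down beside 1 ng/ml, and 3 up and 1 down beside 10 ng/ml (6 up and 3 down blocked). Beside 1 ng/ml the protease median was -0.08 and 0.59 within batches 1 and 2. Only with the culture number as a block there were calls beside 10 ng/ml for cell cycle genes (median -0.20, adjusted p = 0.30, blocked 0.012, or 0.54 with an estimated correlation as well, but 0.13 and 0.33 within batches 1 and 2) and fibroblast markers (4 measured, -0.36, or -0.19 at the bound, adjusted p = 0.097, blocked 0.030, or 0.10), both downward, with 0 members of each called by limma (raw p below 0.05 for 0). Among single genes the interaction at 10 ng/ml was negative with the culture number as a block for MMP9 (-3.94, adjusted p = 2.6e-05), for the immunoproteasome subunit PSMB9 (-2.06, adjusted p = 0.046) and for ISG15, a ubiquitin-like protein induced by interferon (-1.43, adjusted p = 0.046). Without the block their adjusted p was 0.89, 1.00 and 1.00, and with it the interaction of KYNU was positive (2.08, adjusted p = 0.018). MMP9 was called below the sum also with the batch as a block, with log2 and quantile normalized values without background correction, and with replicates 1 to 3 alone. It was not called in the deposited values or without a detection filter. With both blocks together ISG15 lost its call, while MMP9, PSMB9 and KYNU kept theirs.

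The higher TNF-α dose raised lists over the lower dose although limma called 0 of their members over all genes and 0 adjusted over the list alone. These were NF-kB targets (raw p below 0.05 for 2 of 15, median 0.44, adjusted p = 7.2e-12), other chemokines (0 of 6, 0.60, adjusted p = 0.0043) and other cytokines (1 of 12, 0.31, adjusted p = 0.0011), all held with an estimated correlation, although with the culture number as a block as well other cytokines had adjusted p = 0.13. Complement (0.13, or 0.04 at the bound, adjusted p = 0.057) had a call only with the culture number as a block (0.029, or 0.24 with an estimated correlation as well). Interferon-stimulated genes (0.27, adjusted p = 0.0018), proteases (0.15, or 0.11 at the bound, adjusted p = 0.0057) and receptors (0.12, adjusted p = 0.032, blocked 0.10) rose too, but had adjusted p = 0.34, 0.20 and 0.12 with an estimated correlation, with raw p below 0.05 for 0 of 28, 0 of 18 and 1 of 20. Beside IL-17, where limma again called 0 members over all genes, the higher dose raised neutrophil chemokines (raw p below 0.05 for 2 of 5, 1 adjusted over the list alone, 1.16, adjusted p = 2.7e-07) and other cytokines (2 of 12, 1 adjusted over the list alone, 0.77, adjusted p = 3.0e-11), both held with an estimated correlation. NF-kB targets (0.36, adjusted p = 4.0e-08), antimicrobial genes (0.32, or 0.30 at the bound, adjusted p = 3.1e-04), interferon-stimulated genes (0.27, adjusted p = 0.0030), complement (0.19, adjusted p = 0.017), proteases (0.24, adjusted p = 0.016) and receptors (0.15, adjusted p = 0.025) rose there too. Their adjusted p was 0.050, 0.28, 0.36, 0.26, 0.27 and 0.11 with an estimated correlation, with raw p below 0.05 for 3, 1, 0, 0, 0 and 0 members and 0 adjusted over the list alone. Only with the culture number as a block, other chemokines (0.38, or 0.36 at the bound, adjusted p = 0.061, blocked 0.0044, or 0.035 with an estimated correlation as well) and differentiation genes (0.14, or 0.13 at the bound, adjusted p = 0.24, blocked 0.040, or 0.61, and -0.04 and 0.24 within batches 1 and 2) had a call upward and cell cycle genes (-0.12, adjusted p = 0.27, blocked 0.0064, or 0.50, and 0.09 and -0.21 within these batches) downward. Over all genes and adjusted over the list alone limma called 0 members of each of these 3 lists (raw p below 0.05 for 0).

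A larger dose may move the genes that answer to the lower dose further. Of 96 genes called for 1 ng/ml TNF-α with the culture number as a block, 37 (38.5%) moved further at 10 ng/ml in each of 3 replicates and 13 moved back in each. With IL-17, 201 of 473 moved further (42.5%) and 26 back, with a median further change of 0.18, against 0.15 without. Chance gives under 12.5%, since genes picked on the same 1 ng/ml arrays tend to move back. A general dose effect was set beforehand to need over 50% and its absence at most 12.5%. The value lay between, so how many genes follow the dose stays open.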
